A study of Sus scrofa with 12 samples.

How the data were processed

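RNA-seq was performed on porcine muscle satellite cells, the resident stem cells of skeletal muscle, in 12 libraries. They form 4 groups of 3 replicates each. Control cells (WT in the labels, NC in the column names) and cells of the arm named CBP were collected at 0h, labelled as proliferation, and at 60h, labelled as differentiation. The CBP arm was read as cells treated with SGC-CBP30, an inhibitor of the bromodomains of the acetyltransferases CBP and p300, because the protocol states that compound for 48 h in proliferation and for 60 h in differentiation. That treatment text stands on every sample, the controls included, and the group names stand under a genotype tag. The labels therefore leave open whether CBP means a compound or a genetic change, and every value given here for the inhibitor depends on this reading. The dose is written as 5 uM per ml, a unit that mixes concentration and amount, so it is given here only as labelled. The control treatment is not stated, and neither is whether the cells collected at 60h had also met the compound before differentiation. The labels name the cell line C3H, usually a mouse name, while the organism and the genome build are pig. The annotation and gene names used here are those of the pig.

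Libraries were made with the VAHTS Universal V8 kit from total RNA, per the labels' protocols. Reads were trimmed with Trimmomatic and counted with featureCounts on Sscrofa11.1, per the submitters' processing notes, with no versions given. The aligner, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. The authors deposited 1 table of FPKM values (fragments or reads per kilobase of gene, scaled to the library total) with 31908 genes, 1 column per library, and replicates not pooled. A gene symbol was taken from the table for 16801 genes and from the pig reference table, by identifier, for 687. The remaining 14420 kept their identifier. Positions are those of the reference table of Sscrofa11.1.

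Because the authors counted whole reads, the values of a gene are whole multiples of the worth of 1 read in its library. The library totals and gene lengths were recovered from these steps. All 22521 genes above 0 in any library gave whole reads within a tolerance of 0.001, and their sums reached 99.991% to 99.993% of the recovered totals. On simulated values for 22521 genes, 12 of 12 totals, 99.96% of the values and 98.27% of the gene lengths were recovered exactly for genes with a mean of 1 read or more. The recovered reads served for depth, for the number of reads behind a value, for the noise between replicates, and for 1 added alternative. They were not used in the main test, because the deposited unit is FPKM.

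Genes with an FPKM of 1 or more in at least 3 of the 12 libraries were kept, which left 11636. The log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3, as a model of the 4 group means over all 12 libraries with a trended empirical Bayes estimate of the spread. The 5 comparisons were inhibitor against control at 0h, inhibitor against control at 60h, 60h against 0h in control cells, 60h against 0h in inhibitor-treated cells, and the interaction, which is the inhibitor effect at 60h minus that at 0h. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison over the 11636 genes, and a gene was called at an adjusted p under 0.05. All log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Fold values are ratios of group mean FPKM. Each log2 change is given with its standard error (SE) and each mean FPKM with its SD over n = 3 libraries.

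In total, 31 gene lists covering muscle differentiation, cell cycle, chromatin proteins, immune and stress responses, matrix, metabolism and markers of other cell types were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Lists with fewer than 5 tested members (endothelial and immune cell markers, each with 4) were described only. For each list, members called over all genes are given beside the count adjusted over the list alone. The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule takes, per comparison, the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean FPKM of 5 or more in the higher group (for the interaction, in any group) and no overlap between replicates (not required for the interaction). It adds up to 4 called members with the largest change from each list described for a comparison, and always CREBBP, EP300, PAX7, MYF5, MYOD1, MYOG, MYMK, MYH3, CKM, MKI67, CDKN1A and MYC. The lists described for each comparison were chosen after the list results were seen. MKI67 had no match by symbol and was not analysed here. Not every gene that the rule takes is reported here.

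The recovered depth was 16095335 reads (inhibitor 0h, replicate 3) to 19155240 (control 0h, replicate 1). Simulated data with the depth of the real libraries, a coefficient of variation of 2% between libraries and 200 changed genes were fitted in the same way. For the inhibitor at 0h, with 11147 genes tested, 64.6% of genes changed 1.25-fold, 87.7% of those changed 1.5-fold and 96.7% of those changed 2-fold were called in the right direction, with 9 false calls among 10956 unchanged genes. For the interaction, with 11155 genes tested, the shares were 37.5%, 75% and 90.3%, with 11 false calls among 10965. The changed genes were raised and lowered in equal number in 1 group, so the simulation held no shift of all genes. Its false calls therefore do not cover small changes that depend on the scaling of the libraries. Replicates differed by more than read sampling noise in every group (chi-square per degree of freedom 2.16 to 4.65), so none was counted as a duplicate. Beyond counting noise, the median coefficient of variation between replicates was 1.69% to 2.24%. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

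Alternatives were other pseudocounts (0.1 and 0.5), no filter and a stricter one (mean FPKM of 5 or more), rescaling to TPM, by median-of-ratios factors or by quantiles, other settings of the spread (no trend, robust, library weights), a replicate block, only the groups compared, an added minimum log2 change of 1, leaving out each library, and fry for the lists. Voom on the recovered reads was added after the data were seen.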

Results

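Gene expression was measured by RNA-seq in porcine muscle satellite cells, which proliferate as myoblasts and fuse into myotubes when they differentiate. Control cells and cells of an arm labelled CBP, read here as given SGC-CBP30, a small molecule that binds the bromodomains of the histone acetyltransferases CBP and p300, were collected in proliferation (0h) and after 60h of differentiation. Each of the 4 groups held 3 libraries of 16095335 to 19155240 recovered reads, and 11636 genes were tested. The first and second principal components held 49.4% and 34.9% of the variance. The title of the series puts the question as how CBP relates to the differentiation of these cells. Control cells already held high levels of muscle transcripts at 0h, among them MYOG at 343 ± 10.0 FPKM (SD, n = 3).

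In proliferation, muscle genes were lower in inhibitor-treated cells than in control cells. MYOG (ENSSSCG00000034654, chromosome 9, 113783233 to 113785312 in Sscrofa11.1), the transcription factor that drives terminal differentiation of myoblasts, fell 12.03-fold, from 343 ± 10.0 to 28.5 ± 0.996 FPKM (log2 change -3.54, SE 0.032, limma adjusted p = 7.38e-15). The embryonic myosin heavy chain MYH3 fell 14.2-fold (from 163 ± 10.6 to 11.5 ± 1.05 FPKM), skeletal actin ACTA1 fell 15.6-fold, and the fusion protein MYMK (ENSSSCG00000022891, chromosome 1, 273101674 to 273111721) fell 9.05-fold, from 34.5 ± 4.65 to 3.81 ± 0.756 FPKM. Of the 47 tested sarcomere and contractile genes, 42 fell, 1 rose and 4 did not pass (42 and 2 adjusted over the list alone), with a median log2 change of -1.96. The Z-disc protein CSRP3 fell 15.4-fold and cardiac and slow muscle troponin TNNC1 fell 10.1-fold. The list was lower than the other genes by camera (adjusted p = 1.11e-36) and by camera with an estimated correlation (adjusted p = 0.0073).

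Regulators of the muscle lineage moved in the same direction at 0h. Of 21 tested myogenic regulators, 16 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 4.31e-10, and adjusted p = 0.0352 with an estimated correlation). MYOD1, which commits cells to the myoblast state, fell 3.36-fold, from 22.3 ± 0.982 to 6.62 ± 0.75 FPKM. The muscle methyltransferase SMYD1 fell 17.3-fold and TRIM72, a membrane repair protein of muscle, fell 8.78-fold. PAX7 (ENSSSCG00000034627, chromosome 6, 77160827 to 77268626), the marker of satellite cells, fell 1.63-fold (log2 change -0.65, SE 0.053, limma adjusted p = 7.38e-07), and MYF5, a regulator of the undifferentiated myoblast, fell by 0.24 on the log2 scale (-0.38 after median-of-ratios scaling). Among 31 genes of excitation-contraction coupling and muscle energy, 20 fell and 7 rose (20 and 8 adjusted over the list alone; camera adjusted p = 7.81e-08, and adjusted p = 0.0105 with an estimated correlation). Examples were STAC3, needed for coupling of the calcium channel (log2 change -2.49), the sodium channel SCN4A (7.45-fold) and the calsequestrin CASQ2 (3.72-fold). CKM, the muscle creatine kinase, stood at 0.104 FPKM with the inhibitor and 1.33 FPKM in control cells.

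**Figure D1:**
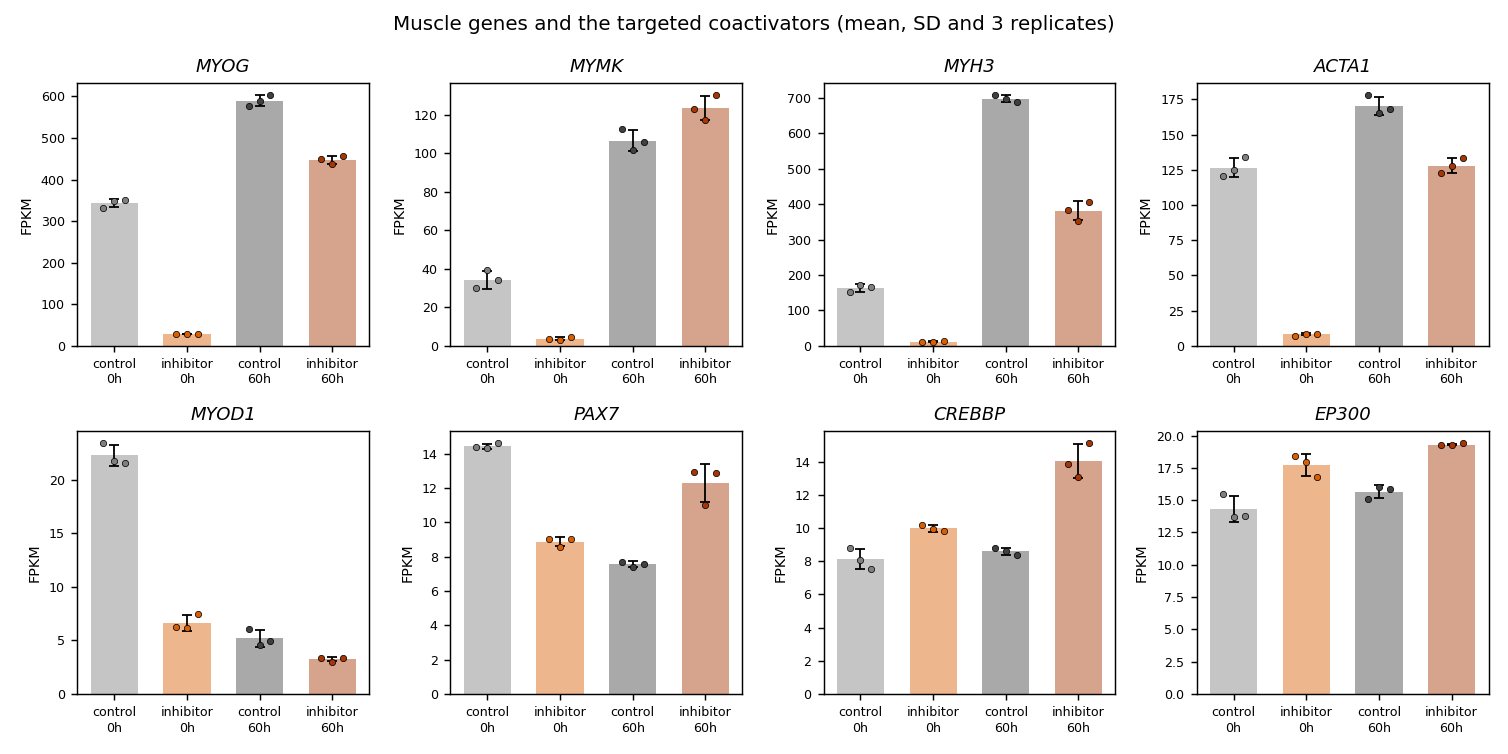
FPKM (linear axis) of 8 genes in control and inhibitor-treated cells at 0h and 60h, with bars for the mean, error bars for the SD and points for the 3 replicates of each group. MYOG was at 343 FPKM in control and 28.5 in inhibitor-treated cells at 0h, and at 589 and 448 FPKM at 60h, while MYMK was at 107 and 124 FPKM at 60h.

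Genes of the extracellular matrix and smooth muscle markers were lower with the inhibitor at 0h as well. Elastin, ELN (ENSSSCG00000025858, chromosome 3, 11214194 to 11245891), fell 18.3-fold, from 53.5 ± 2.26 to 2.92 ± 0.16 FPKM (log2 change -3.79, SE 0.05, limma adjusted p = 1.17e-13). Of 41 tested collagen and matrix genes, 33 fell and 3 rose (33 and 3 adjusted over the list alone), with POSTN down 14.2-fold and COL8A1 down 5.07-fold (camera adjusted p = 1.18e-18, and adjusted p = 0.0307 with an estimated correlation). All 14 tested smooth muscle and pericyte markers fell, also when adjusted over the list alone (camera adjusted p = 5.75e-14, and adjusted p = 0.00659 with an estimated correlation). The smooth muscle actins ACTA2 (from 2571 ± 55.5 to 819 ± 26.8 FPKM) and ACTG2 (7.33-fold), calponin CNN1 (4.59-fold) and the adhesion molecule MCAM (3.42-fold) had the largest changes of this list on the log2(FPKM + 1) scale. Markers of fibroblasts and fibro-adipogenic cells were lower beside them, with 11 of 18 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 1.42e-07, and adjusted p = 0.0352 with an estimated correlation).

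Genes of DNA synthesis and mitosis were higher with the inhibitor at 0h. Of 40 DNA replication genes, 36 rose and none fell, also when adjusted over the list alone (camera adjusted p = 2.62e-09, but adjusted p = 0.0628 with an estimated correlation). The histone chaperone subunit CHAF1B rose 2.06-fold, the origin-binding protein ORC1 2.08-fold, cyclin CCNE2 2.12-fold and the maintenance methylation factor UHRF1 1.96-fold. Of 45 mitosis genes, 44 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.34e-09, but adjusted p = 0.0628 with an estimated correlation), such as the centromeric histone CENPA (2.13-fold) and the kinase AURKB (1.88-fold). In the synthesis of sterols and fatty acids 26 of 30 genes rose and none fell (26 and 1 adjusted over the list alone; camera adjusted p = 2.61e-05, but adjusted p = 0.0884 with an estimated correlation). Fatty acid synthase FASN rose 1.75-fold and the desaturases FADS2 and SCD rose 1.99-fold and 1.72-fold.

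The largest rises at 0h were smaller than the largest falls, ranked here and in the later comparisons by log2(FPKM + 1) among called genes that met the naming rule. The sulfotransferase CHST2 rose 3.93-fold, from 2.92 ± 0.222 to 11.4 ± 0.646 FPKM (log2 change 1.67, SE 0.057, limma adjusted p = 3.93e-10), the secreted glutathione peroxidase GPX3 3.16-fold, the neuropeptide precursor VGF 2.89-fold and the integrin ITGA3 2.58-fold. The small nucleolar RNAs SNORD49A (55 against 17 reads over 3 libraries) and SNORD81 (25 against 8) rose on few reads, and the call of SNORD81 was lost with a pseudocount of 0.1 (adjusted p = 0.199) and after scaling to TPM (adjusted p = 0.0762). The targets of the compound were themselves called. CREBBP, which encodes CBP (ENSSSCG00000007951, chromosome 3, 38388366 to 38530243), rose from 8.13 ± 0.615 to 9.97 ± 0.186 FPKM (log2 change 0.27, SE 0.056), and EP300, which encodes p300 (ENSSSCG00000000068, chromosome 5, 7311165 to 7394515), rose from 14.3 ± 1.02 to 17.7 ± 0.828 FPKM (0.29, SE 0.048). MYC, a growth regulator, fell by 0.21 and the cell cycle inhibitor CDKN1A fell by 0.18 on the log2 scale. The sizes of these small changes depend on scaling: by median of ratios they were 0.14 for CREBBP, 0.16 for EP300, -0.34 for MYC and -0.32 for CDKN1A.

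In all, 5148 genes were higher and 2102 lower with the inhibitor at 0h (limma, adjusted p under 0.05), or 48 higher and 321 lower when a log2 change of at least 1 was also required. The share of higher calls, 71%, became 48.6% (2957 higher, 3131 lower) after median-of-ratios scaling, which moved the median log2 change of all genes by 0.12. Of the lists, 19 of 29 passed camera at 0h and 9 of these with an estimated correlation. Cytosolic ribosomal proteins, with 29 of 49 higher and none lower (29 and none adjusted over the list alone; camera adjusted p = 0.0193, but adjusted p = 0.681 with an estimated correlation), had 2 higher and 1 lower after that scaling and did not pass without control replicate 1 (adjusted p = 0.0758) or inhibitor replicate 1 or 2 (0.0709 and 0.073), so no direction is given for them at 0h.

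After 60h of differentiation, elastin and other matrix genes, interferon-stimulated genes and part of the sarcomere genes were lower in inhibitor-treated than in control cells. ELN fell 67.7-fold, from 117 ± 2.86 to 1.73 ± 0.178 FPKM (log2 change -5.44, SE 0.05, limma adjusted p = 6.17e-15). CRABP2, which carries retinoic acid in the cell, fell 62.1-fold, the small proteoglycan ASPN 33.5-fold, the ammonia transporter RHCG 29.1-fold and the matrix protein FBLN2 19.4-fold. Of 41 collagen and matrix genes, 28 fell and 9 rose (28 and 10 adjusted over the list alone; camera adjusted p = 1.16e-06, but adjusted p = 0.165 with an estimated correlation), among them POSTN (29.9-fold lower) and the microfibril protein MFAP5 (5.29-fold lower). Fibroblast markers were lower beside them in 12 of 18 cases and higher in 4 (12 and 4 adjusted over the list alone; camera adjusted p = 0.000413, but adjusted p = 0.158 with an estimated correlation). Smooth muscle and pericyte markers fell in 10 of 14 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 2.86e-05, but adjusted p = 0.0908 with an estimated correlation).

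Of the 37 interferon-stimulated genes tested, 35 fell with the inhibitor at 60h and none rose, also when adjusted over the list alone, with a median log2 change of -1.61 (camera adjusted p = 1.08e-15, but adjusted p = 0.128 with an estimated correlation). Only 30 of the 37 stayed in the test when any 1 control library at 60h was left out. The rest passed the filter only through those control libraries, where they are high. The ubiquitin-like modifier ISG15 (ENSSSCG00000040575, chromosome 6, 63363201 to 63364211) fell 6.23-fold, from 89.3 ± 8.95 to 14.3 ± 1.74 FPKM. The antiviral proteins IFIT1 (11.12-fold), IFI6 (5.64-fold) and RSAD2 (21.6-fold) fell with it, although reads of IFIT1 can be shared with closely related copies. Of 4 tested immune cell markers, 2 were higher and 1 lower beside them (2 and 2 adjusted over the list alone). Inflammatory and NF-kB target genes fell in 18 of 26 cases and rose in 6, also when adjusted over the list alone (camera adjusted p = 0.000482, but adjusted p = 0.0908 with an estimated correlation). The chemokines CCL5 (22.1-fold) and CXCL8 (19.7-fold) and the cytokine IL6 (18.0-fold) were lower, and the adhesion molecule VCAM1 was 5.59-fold higher.

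Sarcomere genes fell in 40 of 47 cases at 60h and rose in 5, also when adjusted over the list alone, with a median log2 change of -0.99 (camera adjusted p = 2.62e-15, but adjusted p = 0.0908 with an estimated correlation). The actin-binding protein XIRP2 fell 24.0-fold, SMPX 19.7-fold, the slow myosin light chain MYL2 7.74-fold and CSRP3 7.01-fold, whereas MYH3 fell 1.83-fold, from 697 ± 9.81 to 381 ± 26.9 FPKM. MYOG fell 1.32-fold (log2 change -0.40, SE 0.032, limma adjusted p = 3.09e-07) and MYOD1 1.60-fold, while MYMK did not pass the test (log2 change 0.21, SE 0.109, limma adjusted p = 0.102). MYMK passed in a fit of only the groups compared (adjusted p = 0.00455) and after quantile scaling (adjusted p = 0.0498). PAX7 rose 1.62-fold, from 7.57 ± 0.158 to 12.3 ± 1.11 FPKM. MYF5 rose by 0.22 on the log2 scale (adjusted p = 0.000768), a call lost after median-of-ratios scaling (0.09, adjusted p = 0.0735). Among 21 myogenic regulators 9 rose and 10 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.291). ID1, which holds back basic helix-loop-helix factors, rose 3.41-fold, and SMYD1, TRIM72 and MYF6 fell 5.11-fold, 2.97-fold and 15.4-fold. MYF6 was low in both groups (2.03 FPKM in control cells).

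**Figure D2:**
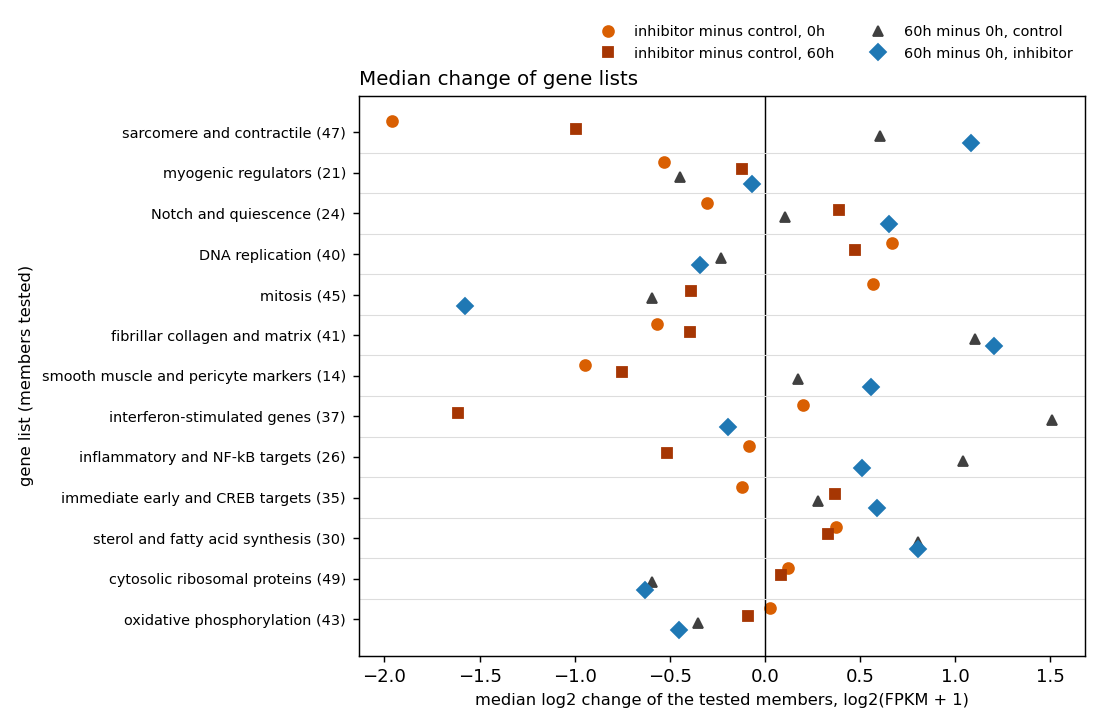
Median log2 change, in log2(FPKM + 1), of the tested members of 13 gene lists (number tested in brackets) in the 4 comparisons, with a symbol per comparison and the line at no change. The sarcomere median was -1.96 with the inhibitor at 0h and -0.99 at 60h, and the interferon median was 1.51 from 0h to 60h in control cells and -0.19 in inhibitor-treated cells. For cytosolic ribosomal proteins, the medians of 0.12 and 0.09 with the inhibitor became -0.02 and -0.04 after median-of-ratios scaling, that of oxidative phosphorylation at 0h went from 0.03 to -0.11, and that of myogenic regulators from 0h to 60h with the inhibitor went from -0.07 to 0.002.

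Cell cycle genes parted at 60h. DNA replication genes were higher with the inhibitor in 34 of 40 cases and lower in 2 (35 and 2 adjusted over the list alone; camera adjusted p = 1.42e-05, but adjusted p = 0.165 with an estimated correlation), such as the transcription factor E2F1 (2.44-fold) and the replication clamp PCNA (1.92-fold). Mitosis genes were lower in 33 of 45 cases and higher in 3, also when adjusted over the list alone (camera adjusted p = 1.31e-07, but adjusted p = 0.158 with an estimated correlation). The ubiquitin-conjugating enzyme UBE2C fell 2.72-fold, the kinesin KIF20A 2.32-fold and cyclin CCNB1 2.15-fold. Genes of Notch signalling and quiescence were higher in 17 of 24 cases and lower in 4 (18 and 4 adjusted over the list alone; camera adjusted p = 0.024, but adjusted p = 0.226 with an estimated correlation), with VCAM1 at 5.59-fold, the chemokine receptor CXCR4 at 3.27-fold, the cell cycle inhibitor CDKN1C at 3.07-fold and the receptor FGFR4 at 2.41-fold. At 0h the same list had gone the other way, with 15 genes lower and 5 higher, also when adjusted over the list alone (camera adjusted p = 1.22e-05, and adjusted p = 0.0398 with an estimated correlation). Acetyltransferases, deacetylases and bromodomain proteins rose in 36 of 49 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.000763, but adjusted p = 0.165 with an estimated correlation), and in 30 and 6 cases after median-of-ratios scaling. BRD2 rose 1.88-fold, EZH2 1.84-fold, HDAC3 1.76-fold, CREBBP 1.63-fold and EP300 1.23-fold (log2 change 0.29, and 0.17 after median-of-ratios scaling), and HDAC9 fell 5.50-fold.

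On the log2(FPKM + 1) scale, the largest rises at 60h were in the sulfotransferase SULT1A3 (19.1-fold), CD24 (12.1-fold), SESN3 (9.42-fold), ARMH4 (9.31-fold), the oxygenase CYP1B1 (7.86-fold, from 9.76 ± 0.373 to 76.7 ± 1.23 FPKM) and GPX3 (6.37-fold). SULT1A3 belongs to a family of near copies and its reads are uncertain. MYC fell by 0.42 and CDKN1A by 0.41 on the log2 scale, and CKM fell 1.58-fold. In all, 5200 genes were higher and 3137 lower (296 and 582 with a log2 change of at least 1), and 18 of 29 lists passed camera, none of them with an estimated correlation. The share of higher calls, 62.4%, became 48.4% (3899 higher, 4155 lower) after median-of-ratios scaling, which moved the median of all genes by 0.11.

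From 0h to 60h, control cells gained transcripts of the sarcomere, the matrix and the interferon response and lost those of mitosis and ribosomes. The collagen chain COL6A3 (ENSSSCG00000027331, chromosome 15, 137011549 to 137103687) rose 28.0-fold, from 8.54 ± 0.67 to 239 ± 8.34 FPKM (log2 change 4.66, SE 0.045, limma adjusted p = 1.67e-14). MYH3 rose 4.27-fold, cardiac troponin TNNT2 6.89-fold, the embryonic light chain MYL4 7.12-fold, MYMK 3.10-fold, CKM 5.27-fold and MYOG 1.72-fold. PAX7 fell 1.91-fold, MYF5 1.56-fold and MYOD1 4.29-fold. Of 47 sarcomere genes 28 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 1.01e-05, but adjusted p = 0.219 with an estimated correlation).

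Of 41 collagen and matrix genes 35 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 4.48e-17, but adjusted p = 0.0743 with an estimated correlation), among them COL12A1 (5.61-fold), tenascin TNC (5.01-fold) and CTHRC1 (22.1-fold). Fibroblast markers were higher beside them in 13 of 18 cases and lower in 3, also when adjusted over the list alone (camera adjusted p = 1.52e-05, but adjusted p = 0.0859 with an estimated correlation). Interferon-stimulated genes rose in 35 of 37 cases and fell in none, also when adjusted over the list alone (camera adjusted p = 2.50e-16, but adjusted p = 0.0859 with an estimated correlation). ISG15 rose 32.1-fold, from 2.79 ± 0.503 to 89.3 ± 8.95 FPKM, IFI6 48.5-fold and MX1 15.5-fold, and RSAD2 went from 7 to 1990 reads. Of 4 tested immune cell markers, 1 was higher and 3 were lower beside them, also when adjusted over the list alone, with a median log2 change of -1.04. The zinc finger factor EGR1 rose 44.0-fold, from 3.73 ± 0.202 to 164 ± 0.446 FPKM, and 20 of 35 immediate early and CREB target genes rose while 9 fell, also when adjusted over the list alone (camera adjusted p = 0.00117, but adjusted p = 0.0999 with an estimated correlation), including JUNB (11.04-fold) and FOS (11.8-fold). EGR2 rose from 0.151 to 9.89 FPKM. Sterol and fatty acid synthesis genes rose in 28 of 30 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 5.72e-13, but adjusted p = 0.0504 with an estimated correlation), with SCD up 3.17-fold and the sterol oxidase MSMO1 up 2.37-fold.

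Mitosis genes fell in 44 of 45 cases in control cells and rose in none, also when adjusted over the list alone, with a median log2 change of -0.59 (camera adjusted p = 2.31e-11, but adjusted p = 0.0859 with an estimated correlation). UBE2C fell 2.19-fold, NEK2 2.10-fold and the kinase CDK1 2.03-fold. All 49 cytosolic ribosomal protein genes fell, also when adjusted over the list alone, and under median-of-ratios scaling (camera adjusted p = 1.32e-15, but adjusted p = 0.194 with an estimated correlation), with RPS6 from 361 ± 7.18 to 191 ± 3.04 FPKM. On the log2(FPKM + 1) scale, which ranks genes otherwise than the fold of FPKM, the largest falls were in CYP1A1, a monooxygenase induced by the aryl hydrocarbon receptor (20.4-fold, from 26.3 ± 1.9 to 1.29 ± 0.172 FPKM), the anion exchanger SLC4A3 (6.63-fold), BLVRB (5.88-fold), TSPAN15 (5.85-fold) and the quinone reductase NQO1 (5.84-fold). The microRNA gene ssc-mir-10383 fell on 33 against 2 reads. RHCG rose 46.4-fold, MYC 2.18-fold and CDKN1A 1.12-fold. EP300 rose by 0.12 on the log2 scale (limma adjusted p = 0.0394), a call lost without control replicate 2 or 3 at 0h (adjusted p = 0.147 and 0.132) or at 60h (0.113 and 0.099) and without inhibitor replicate 1 or 3 at 60h (0.0503 and 0.0501). CREBBP did not pass (0.07, limma adjusted p = 0.273), but did so after scaling to TPM (adjusted p = 0.0392) or by median of ratios (adjusted p = 0.0473). In all, 3351 genes rose and 4424 fell (428 and 311 with a log2 change of at least 1). The share of rises, 43.1%, became 53.3% after scaling to TPM (4090 rose, 3580 fell). Of 29 lists 16 passed camera, and the inflammatory and NF-kB targets (21 of 26 higher and 1 lower, also when adjusted over the list alone) also passed with an estimated correlation (adjusted p = 0.0215).

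In inhibitor-treated cells, sarcomere genes were higher at 60h than at 0h, where their muscle transcripts were below those of control cells. It is not stated whether the cells collected at 60h had met the compound before differentiation. The rises and falls given here may therefore not be the course of cells that began from the inhibitor-treated state at 0h. MYOG rose 15.7-fold, from 28.5 ± 0.996 to 448 ± 9.5 FPKM (log2 change 3.93, SE 0.032, limma adjusted p = 2.25e-15), MYMK 32.5-fold, MYH3 33.1-fold, TNNT2 51.9-fold, MYL4 45.0-fold and the perinatal myosin MYH8 40.4-fold. Of 47 sarcomere genes 40 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 3.24e-12, but adjusted p = 0.0679 with an estimated correlation). PAX7, which fell in control cells, rose 1.38-fold with the inhibitor. CREBBP rose 1.41-fold, MYOD1 fell 2.04-fold and MYC rose 1.88-fold. CKM rose from 0.104 to 4.44 FPKM. EP300 rose by 0.12 on the log2 scale (limma adjusted p = 0.043), a call lost when any 1 of inhibitor replicates 2 and 3 at 0h (adjusted p = 0.0636 and 0.165), inhibitor replicates 1, 2 and 3 at 60h (0.0815, 0.0782 and 0.0901) or control replicates 2 and 3 at 60h (0.0506 and 0.0524) was left out. With a replicate block its adjusted p was 0.0527, and by median of ratios its log2 change was 0.19. MYF5 fell by 0.17 on the log2 scale (-0.10 by median of ratios), a call lost after scaling to TPM (adjusted p = 0.263), and CDKN1A did not pass (-0.07, limma adjusted p = 0.116). Notch and quiescence genes rose in 18 of 24 cases and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.000246, but adjusted p = 0.0679 with an estimated correlation), among them HEYL (15.3-fold), VCAM1 (11.6-fold), CDKN1C (11.02-fold) and HES6 (7.62-fold).

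Mitosis genes fell in 44 of 45 inhibitor-treated cases and rose in 1, also when adjusted over the list alone, with a median log2 change of -1.57 (camera adjusted p = 4.29e-16, and adjusted p = 0.0404 with an estimated correlation). UBE2C fell 7.63-fold, from 97.7 ± 4.59 to 12.8 ± 1.52 FPKM, CCNB1 6.26-fold, KIF20A 5.58-fold and CDC20 5.26-fold. Immediate early and CREB target genes rose in 26 of 35 cases and fell in 7, also when adjusted over the list alone (camera adjusted p = 2.27e-06, and adjusted p = 0.0404 with an estimated correlation). EGR1 rose 109-fold and FOS 37.9-fold, and EGR2 and EGR3 rose to 16.4 and 12.2 FPKM from levels that rested on 9 and 3 reads. COL6A3 rose 40.1-fold. Ranked by log2(FPKM + 1) and not by fold, the largest falls were in the growth factor FGF19 (from 19.0 ± 0.899 FPKM to a level of 5 reads), the mitochondrial carrier UCP2 (25.7-fold), the chloride channel ANO1 (from 10.7 to 0.155 FPKM), NQO1 (17.7-fold), CYP1A1 (14.4-fold) and the matrix protein LTBP2 (11.2-fold). In all, 3638 genes rose and 4826 fell (566 and 562 with a log2 change of at least 1). The share of rises, 43%, became 54.6% after scaling to TPM (4557 rose, 3794 fell). Of 29 lists 17 passed camera and 5 of these with an estimated correlation.

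**Figure D3:**
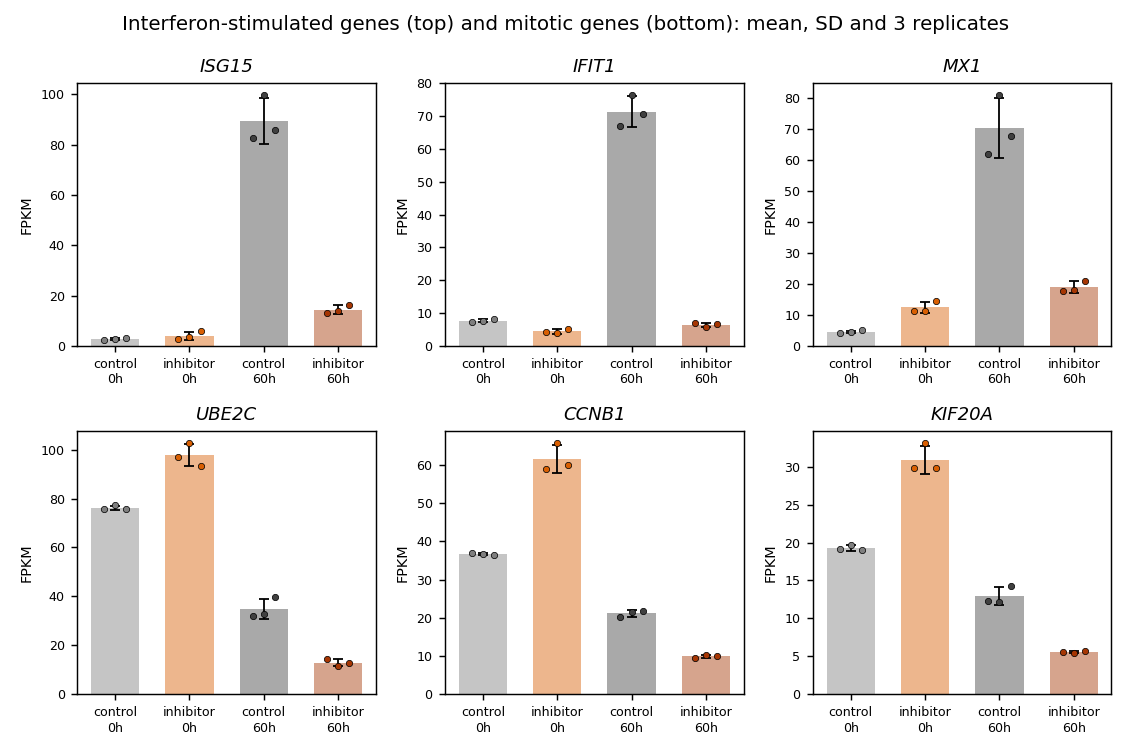
FPKM (linear axis) of 3 interferon-stimulated genes (top) and 3 mitotic genes (bottom) in control and inhibitor-treated cells at 0h and 60h, with bars for the mean, error bars for the SD and points for the 3 replicates of each group. ISG15 was at 2.79 and 4.04 FPKM at 0h in control and inhibitor-treated cells and at 89.3 and 14.3 FPKM at 60h, and UBE2C was at 76.2 and 97.7 FPKM at 0h and at 34.8 and 12.8 FPKM at 60h.

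The effect of the inhibitor itself differed between 0h and 60h for many of these genes, by the interaction term. The protocol gives the compound for 48 h in proliferation and 60 h in differentiation, and earlier exposure of the 60h cells is not stated. Stage and exposure can therefore not be told apart in this term. MYOG (log2 interaction 3.15, SE 0.045, limma adjusted p = 8.92e-13), MYMK (3.10), ACTA1 (3.40), MYH8 (3.22), TNNT2 (2.87) and MYH3 (2.84) had positive interactions, which for MYOG, ACTA1 and MYH3 is a smaller reduction at 60h than at 0h. Of 47 sarcomere genes 32 had a positive and 11 a negative interaction (32 and 12 adjusted over the list alone; camera adjusted p = 2.42e-07, but adjusted p = 0.197 with an estimated correlation). Of 21 myogenic regulators 19 were positive and 1 negative (19 and 2 adjusted over the list alone; camera adjusted p = 2.42e-07, but adjusted p = 0.108 with an estimated correlation), including PAX7 (1.27), TRIM72 (1.33), MYOD1 (1.07) and MYF5 (0.46). Of 24 Notch and quiescence genes 16 were positive and 1 negative, also when adjusted over the list alone (camera adjusted p = 2.42e-07, and adjusted p = 0.0487 with an estimated correlation), including CDKN1C (3.51), FGFR4 (2.46), DLL1 (2.09) and HES6 (1.95). Of 45 mitosis genes 44 were negative and 1 positive, also when adjusted over the list alone (camera adjusted p = 3.71e-18, and adjusted p = 0.0487 with an estimated correlation), including CCNB1 (-1.76), KIF20A (-1.74), UBE2C (-1.73) and CENPA (-1.70).

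Interferon-stimulated genes had negative interactions in 35 of 37 cases and positive ones in none (36 and none adjusted over the list alone; camera adjusted p = 3.81e-18, but adjusted p = 0.0963 with an estimated correlation). RSAD2 (-3.48), MX1 (-3.10), IFI6 (-3.07) and ISG15 (-2.93) were the largest, beside the matrix protein FBLN2 (-3.78), RHCG (-3.60) and the endothelial proteoglycan ESM1 (-3.24). CREBBP had a positive interaction (0.38, SE 0.079, limma adjusted p = 0.0017), as did CKM (0.52), while MYC (-0.21) and CDKN1A (-0.24) had negative ones and EP300 did not pass (adjusted p = 0.96). The microRNA gene MIR1-2 had a positive interaction (3.75) that rested on 29 reads with the inhibitor and 4 in control cells at 60h, and on 0 and 14 reads at 0h, where control replicate 3 alone stood at 6.79 FPKM. In all, 2823 genes had a positive and 3104 a negative interaction (266 and 354 with a log2 interaction of at least 1 in size), and 15 of 29 lists passed camera, 3 of them with an estimated correlation.

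Genes that responded to the inhibitor at 0h overlapped with those that responded at 60h, 2 comparisons that share no library. There were 3387 genes higher at both stages where independent lists would share 2301, and 1403 lower at both where independent lists would share 567. Among genes with a log2 change of at least 1 in both, 16 were higher and 171 lower, ELN, POSTN, MFAP5 and CSRP3 among the latter. In opposite directions, 631 genes were higher at 0h and lower at 60h and 366 the reverse (1388 and 939 for independent lists). Across the 11636 genes, which are not independent replicates, the log2 changes at the stages had a Pearson r of 0.537 and a Spearman rho of 0.486. These counts depend on the shift of all genes, and after median-of-ratios scaling 1850 were higher and 2121 lower at both stages.

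Genes that changed during differentiation of control cells were compared with the interaction, to ask whether the inhibitor weakened that change. Of the 3351 genes that rose in control cells, 1262 had a negative interaction, as did the interferon genes ISG15 and MX1, and 791 had a positive one, as did MYOG and MYH3. Of the 4424 that fell, 1311 had a positive interaction, as did PAX7 and MYOD1, and 1047 a negative one, as did UBE2C and CCNB1. Independent lists would share 894 and 1073 genes with an interaction against the change. Both quantities use the control libraries, and in 20 simulations without any interaction the mean counts were 0.1 and 0, with maxima of 1 and 0. The simulations keep the changes with stage and treatment and the shared libraries but hold no interaction. Almost no gene could therefore be called for an interaction in them, and counts near 0 were fixed in advance. They do not measure how far the shared controls tilt the direction of called interactions, and they lend no weight to the observed counts. The expected numbers leave out the shared libraries. Part of the excess over the expected numbers may therefore come from the shared controls.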

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

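The tests of explanations for the 3 patterns below were chosen after the results were seen, whereas the regroupings of libraries were planned, apart from the division of the relabellings by whether they keep the treatment groups. The lists and genes with an interaction value in this part were singled out because the inhibitor effect at 60h differed from that at 0h by the interaction term, as it did in 5927 genes. The excess of higher over lower genes at 0h is a comparison within 0h and no interaction result.

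Sarcomere genes were lower with the inhibitor at 0h, and their median interaction was 0.62 (adjusted p = 0.197 with an estimated correlation). More fibroblast-like cells in the inhibitor cultures would raise fibroblast markers, and their median was -0.60. This does not decide on that account, because 33 of 41 collagen and matrix genes were lower at 0h too. A lower level of such genes per cell could hide a larger share of these cells. After median-of-ratios scaling 43 of 47 genes were lower. That scaling lowered the inhibitor values at 0h by a median of 0.12, so this count could not have gone against the pattern. The sarcomere median of -1.96 was larger in size than that shift. Fewer differentiating cells among the muscle cells would leave PAX7 and MYF5 of undifferentiated cells no lower. Both were lower (-0.65 and -0.24), against that prediction, but the compound may act on these 2 genes directly. Replication genes (36 of 40, none lower) and mitosis genes (44 of 45, 1 lower) were higher at 0h, the direction of this account. Their camera adjusted p with an estimated correlation was 0.0628 for each. The values point both ways and no table decides how many cells had begun to differentiate, so this account stays open. A direct effect of the compound on the sarcomere genes is not separated from either account.

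Interferon-stimulated genes rose to 60h in control cells and were lower with the inhibitor at 60h, with a median interaction of -1.86 (adjusted p = 0.0963 with an estimated correlation). Immune cells in the 60h control cultures are argued against by PTPRC, which had 2 reads in all libraries together. The median of the 4 tested immune markers was -1.04, but CD14 among them rose in control cells, from 1.63 to 2.31 FPKM. Markers below the filter went both ways there, such as ITGAM (from 0.108 to 0.517 FPKM) and CD79A (from 0.332 to 0.0895), so the median alone decides little. After median-of-ratios scaling 35 of 37 genes were lower with the inhibitor at 60h. That scaling lowered the inhibitor values there by a median of 0.11, so this count could not have gone against the pattern. The list median of -1.61 at 60h was larger in size than that shift. A single library is argued against by the lowest share over the leave-outs, 90% (27 of 30 tested). Only 30 of the 37 were tested when any 1 control library at 60h was left out. The rest passed the filter only through the control libraries at 60h, which favours this pattern, so they add no support for it. An effect of the inhibitor on an interferon response in the muscle cells may therefore be a hypothesis to follow, found and examined on the same data.

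More genes were higher than lower with the inhibitor at 0h. Reads freed by the 321 genes that fell by 1 or more on the log2 scale could add 0.062 to all other genes, against a median change of 0.12 over all genes. Genes that fell by less were not counted, so 0.062 is no upper limit and library composition stays open. After median-of-ratios scaling the median was 0.001 and the share of higher calls 48.6%, so the excess depends on scaling. A trend with gene length across genes is argued against by a Spearman rho of -0.045, which gives every gene the same weight whatever its abundance. After scaling to TPM the share of higher calls was 65.7% (4458 higher, 2323 lower). The shallowest library is argued against by a share of 69.9% higher without it. A change in the RNA content of the cells was not tested.

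Among list medians of the interaction, myogenic regulators were at 0.46, dystrophin complex and basement membrane at 0.28, Notch and quiescence at 0.71, acetyltransferases, deacetylases and bromodomain proteins at 0.085, immediate early and CREB targets at 0.37, and muscle atrophy and autophagy at 0.28 (camera adjusted p = 0.0349, and 0.0514 without inhibitor replicate 2 at 60h; adjusted p = 0.197 with an estimated correlation). Mitosis was at -0.96, inflammatory and NF-kB targets at -0.42, the integrated stress response at -0.32, p53 targets at -0.24, oxidative phosphorylation at -0.14, mitochondrially encoded genes at -0.59, and heat shock and proteasome at -0.23. Of these lists, only the dystrophin complex and basement membrane, Notch and quiescence, and mitosis passed with an estimated correlation (adjusted p = 0.0487 for each). The others had an adjusted p with an estimated correlation of 0.108 for myogenic regulators, 0.279 for acetyltransferases, deacetylases and bromodomain proteins, 0.0963 for immediate early and CREB targets, 0.185 for inflammatory and NF-kB targets, 0.279 for the integrated stress response, 0.197 for p53 targets, 0.322 for oxidative phosphorylation, 0.197 for mitochondrially encoded genes and 0.322 for heat shock and proteasome.

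Single genes had positive log2 interactions for MYF5 (0.46), CREBBP (0.38), CKM (0.52), MIR1-2 (3.75, on 29 and 4 reads at 60h and 0 and 14 at 0h), MYMK (3.10), MYOG (3.15), CDKN1C (3.51), ACTA1 (3.40), MYH8 (3.22), TRIM72 (1.33), MYOD1 (1.07), PAX7 (1.27), FGFR4 (2.46), HES6 (1.95), DLL1 (2.09), TNNT2 (2.87) and MYH3 (2.84). They were negative for CDKN1A (-0.24), MYC (-0.21), RHCG (-3.60), FBLN2 (-3.78), ESM1 (-3.24), RSAD2 (-3.48), MX1 (-3.10), IFI6 (-3.07), ISG15 (-2.93), UBE2C (-1.73), KIF20A (-1.74), CCNB1 (-1.76) and CENPA (-1.70).

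Of 100 relabellings of the treatment within the stages, the real one included, 1 gave as many genes with an interaction (5927, the highest other 5134). However, 85 of the 100 mix control and inhibitor libraries at both stages and called at most 1 gene, because the mixing widens the spread within groups. The 15 that keep the treatment groups at a stage, the real one included, are too few for a share under 0.05, so this comparison does not decide on chance. For the overlap of the inhibitor effects 1 of 100 gave as large a count (4790, the highest other 0). Mixed groups call almost no genes at their stage, so an overlap could not arise in them and this comparison decides nothing either. For the lists with an interaction, 30 of 100 gave as many (15, the highest other 22), and for genes with an interaction against their change in control cells 5 of 100 did (2573, the highest other 3026). Every other draw that reached 2573 kept the treatment groups at 60h, and with them the inhibitor effect at that stage. Lists also passed in mixed draws that called 0 genes, as with 17 lists in 1 draw. Neither comparison therefore decides on chance, which is not excluded for either count. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. As many genes were called in 1 of 10 splits for each, with 7250 genes and 0 at most elsewhere for the inhibitor at 0h, 8337 and 0 at 60h, 7775 and 0 for control differentiation, and 8464 and 1 for inhibitor-treated differentiation. As many lists passed in 3 of 10 splits at 0h (19, the highest other 20), 2 at 60h (18 and 18), 2 in control differentiation (16 and 16) and 2 in inhibitor-treated differentiation (17 and 17).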

How the results depend on the processing

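Voom on the recovered reads was chosen after seeing the data; the other alternatives were planned. Requiring a log2 change of at least 1 left 369, 878, 739, 1128 and 620 genes for the inhibitor at 0h, the inhibitor at 60h, control differentiation, inhibitor-treated differentiation and the interaction, 187 genes in the overlap of inhibitor effects and 172 with an interaction against their change in control cells. In the same order, lists passing camera fell to 9, 0, 1, 5 and 3 with an estimated correlation, while fry, which does not compare a list with other genes, called 28, 28 and 26 in the last 3. Leaving out 1 library gave 6670 to 7222, 7822 to 8337, 7240 to 7796, 7981 to 8418 and 5455 to 5756 genes, 4473 to 4641 in the overlap and 2298 to 2518 against the change. Lists then ranged over 17 to 21, 18, 16, 17 and 14 to 17, and none turned direction. Lists that gained a call in some leave-outs were cell cycle exit and Schwann and neural markers for the inhibitor at 0h (lowest adjusted p = 0.0395 and 0.0406), and for the interaction excitation-contraction coupling (0.0421), the neuromuscular junction (0.0238) and smooth muscle markers (0.035). Voom called 6304, 8113, 7770, 8511 and 5997 genes.

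Replicate numbers did not pair the libraries: residuals of the same number correlated at -0.094 to 0.082, and 2 of 12 libraries correlated best with their own number. With a replicate block 7182, 8270, 7721, 8387 and 5796 genes were called, and list counts stayed at 19, 18, 16, 17 and 15. The 211 named gene comparisons were followed under the alternatives other than fry and the added minimum log2 change (5206 values). Of these values, 5163 kept direction and side of the threshold, 25 lost and 5 gained a call, 13 uncalled values moved, and 0 reversed. The causes were not tested. Depth limits SNORD81, MIR1-2 and ssc-mir-10383, which rest on few reads.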

Other observations

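The named examples in this part were chosen after their values were seen, and so were the tests of both hypotheses. The basement membrane collagen genes COL4A1 and COL4A2 rose with differentiation and were higher with the inhibitor at 60h. COL4A1 went from 171 to 503 FPKM in control cells and from 113 to 986 in inhibitor-treated cells, and COL4A2 from 125 to 255 and from 92.5 to 517. In their list, the dystrophin complex and basement membrane, 15 of 23 genes fell and 3 rose with the inhibitor at 0h (15 and 5 adjusted over the list alone; limma camera adjusted p = 8.06e-07, and adjusted p = 0.00659 with an estimated correlation), but the list did not pass at 60h (12 rose and 9 fell, also when adjusted over the list alone; camera adjusted p = 0.84) or in control differentiation (11 rose and 8 fell, also when adjusted over the list alone; camera adjusted p = 0.213). Myostatin, MSTN, which limits muscle growth, was at 5.07 FPKM in control and 20.99 in inhibitor-treated cells at 60h, and the growth factor binding protein IGFBP5 at 131 and 22.5. Their list of TGF-beta, myostatin and IGF signalling fell in 17 of 33 cases and rose in 6 at 0h (also when adjusted over the list alone; camera adjusted p = 2.42e-05, and adjusted p = 0.0073 with an estimated correlation). At 60h 19 were lower and 12 higher, also when adjusted over the list alone (camera adjusted p = 0.0369, but adjusted p = 0.15 with an estimated correlation and 0.152 after median-of-ratios scaling). The acetylcholine receptor CHRNA1 was at 219 and 47.0 FPKM at 0h, in a neuromuscular junction list with 5 of 10 lower and 3 higher (also when adjusted over the list alone; camera adjusted p = 0.0181, but adjusted p = 0.0628 with an estimated correlation), which did not pass without control replicate 1, 2 or 3 at 0h (adjusted p = 0.0526, 0.0507 and 0.0588) or after median-of-ratios scaling (0.0547). Fusion and adhesion genes fell in 11 of 21 cases and rose in 9 at 0h (also when adjusted over the list alone; camera adjusted p = 0.0187, but adjusted p = 0.138 with an estimated correlation and 0.0573 after median-of-ratios scaling).

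In metabolism and stress, 37 of 43 oxidative phosphorylation genes fell and 1 rose in control differentiation (also when adjusted over the list alone; limma camera adjusted p = 1.79e-07, but adjusted p = 0.1004 with an estimated correlation), while 10 of 13 mitochondrially encoded genes rose and 3 fell (also when adjusted over the list alone; camera adjusted p = 0.0166, but adjusted p = 0.453 with an estimated correlation). Together, the mitochondrially encoded genes did not gain reads: their share was 3.7% (SD 0.08) in control cells at 0h and 3.51% (SD 0.09) at 60h. The chaperone HSPA5 rose from 194 to 632 FPKM in control cells, and its list of the integrated stress response and unfolded protein response had 17 of 25 lower and 6 higher with the inhibitor at 60h (also when adjusted over the list alone; camera adjusted p = 0.000112, but adjusted p = 0.164 with an estimated correlation). The p53 target GDF15 was at 41.6 FPKM in control and 5.97 in inhibitor-treated cells at 60h, with 10 of 20 p53 targets lower and 5 higher (also when adjusted over the list alone; camera adjusted p = 0.0118, but adjusted p = 0.226 with an estimated correlation). Heat shock and proteasome genes were lower in 15 of 21 cases and higher in 4 at 60h (also when adjusted over the list alone; camera adjusted p = 0.0013, but adjusted p = 0.181 with an estimated correlation), with CRYAB at 430 and 149 FPKM. Muscle atrophy and autophagy genes rose from 0h to 60h in inhibitor-treated cells in 11 of 13 cases and fell in none (also when adjusted over the list alone; camera adjusted p = 4.65e-05, and adjusted p = 0.0404 with an estimated correlation), including CTSL from 6.38 to 21.4 FPKM. In control cells 9 rose and 2 fell (also when adjusted over the list alone; camera adjusted p = 0.00197, but adjusted p = 0.0859 with an estimated correlation), and for the inhibitor against control at 60h the list did not pass (9 higher, 2 lower, or 10 and 2 adjusted over the list alone; camera adjusted p = 0.308). Cell cycle exit genes (adjusted p = 0.956), glycolysis and hypoxia (0.381), adipocyte markers (0.84) and Schwann and neural markers (0.938) did not pass camera for the inhibitor against control at 60h. Of 4 tested endothelial markers, 2 were higher and 2 lower there, also when adjusted over the list alone.

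The falls of NQO1 and BLVRB with differentiation raised the hypothesis of a fall of NRF2-dependent transcription. Of 16 other NRF2 targets tested in control cells, 16 were lower at 60h, with a median log2 change of -0.89. Among 10000 random lists the 95th percentile was 11 and the highest 14. This is consistent with the hypothesis, but activity of NRF2 was not measured, and it remains a hypothesis examined on the data that raised it. Of 6 aryl hydrocarbon receptor targets, 6 fell in control differentiation, and 4 were higher and 1 lower with the inhibitor at 60h.

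HEXIM1, an inhibitor of transcription elongation that is known to rise with inhibitors of BET bromodomain proteins, was at 38.8 FPKM in control and 84.2 in inhibitor-treated cells at 0h, and at 49.2 and 144 at 60h. The hypothesis of a response shared with BET inhibitors was examined in 15 histone-named genes, of which 86.7% were higher with the inhibitor at 60h against 44.6% of other genes (Fisher's exact p = 0.00115), and 13 after median-of-ratios scaling. MYC was lower (-0.42). Histone genes are near copies of each other, so their reads are uncertain, and with 1 compound an effect through CBP and p300 may give the same values.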
